A study of Homo sapiens with 8 samples.

How the data were processed

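RNA of End1/E6E7 cells, infected with Chlamydia trachomatis L2 or left uninfected, was measured at 24 h and 48 h on 2-colour arrays, with 2 biological replicates of each state and time and technical dye swaps, 8 arrays in all on 2 slides. Each slide held the 4 arrays of 1 replicate number, so replicate and slide coincide, and both slides were scanned on 1 day. Per the file headers the arrays were of Agilent design 14850, with 45015 spots, while the series text names another custom design; the values were read with the probe names in the scanner files.

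The deposited scanner files hold spot and background signals in units of intensity, made by the authors with Agilent Feature Extraction 10.5.1.1 with spatial detrending on and not normalised. The deposited processed signals are intensity values that the scanner software background-subtracted and dye-normalised. The deposited log ratio of the same files is the log10 of processed red over processed green. The authors' value table is, judged from its values, a log2 ratio of red over green per array, centred near 0 (array medians from 6e-07 to 0.0152). The submitters' notes name limma with no settings. Across probes the authors' log2 values had a Pearson r between 0.967 and 0.977 with the scanner's log ratio and between 0.995 and 0.998 with the loess values computed here.

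Mean signals were background-corrected by normexp with an offset of 50 and normalised within each array by loess, with the 1639 control spots at weight 0. Spots marked as outliers by the scanner (91 to 320 per array) and control spots were left out, and spots of the same probe were averaged, which gave 41000 probes from 43376 spots. Ratios were turned to infected over uninfected, and the 2 arrays of a dye swap were averaged, which left 4 columns of values. A probe was kept when it was well above background in all 4 channel measurements of at least 1 of the 4 conditions (34558 probes). Background medians lay between 27 and 44 in Cy3 and between 83.5 and 90.5 in Cy5.

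Gene symbols came from a current RefSeq table used for names only: 26222 probes matched by accession, 1646 by current symbol and 466 by synonym, and 12666 had no match, which gave 18450 distinct symbols. Of the probes of a gene, the one with the highest mean log2 intensity over all arrays was used, and the other probes are given as a comparison. Probe positions are those of the deposited annotation, on hg19.

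The 4 columns were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per time, moderated by eBayes (2 residual degrees of freedom, prior 2.92), and p-values were adjusted by the Benjamini-Hochberg method over 16383 genes with a threshold of 0.05. The contrasts were infected against uninfected at 24 h and at 48 h and the difference between them. For uninfected cells over time, separate channels were normalised between arrays, the red and green values of each extract were averaged, and limma was fitted to the 8 extracts. With 2 replicates per group the numbers do not pair samples by themselves. The deviations of same-numbered columns had a correlation of 0.447 across genes, so values with the replicate number as a block are given beside the counts.

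Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists of a contrast, and again with an estimated correlation. The lists were immediate-early and ERK feedback genes, ETS family transcription factors, mesenchymal genes of EMT, epithelial junction and keratin genes, TGF-beta and YAP targets, inflammatory cytokines and NF-kB targets, type I interferon-stimulated genes and antigen presentation genes. Further lists held cholesterol synthesis and uptake, hypoxia and glycolysis, ATF4 response, ER chaperone, p53 target, G2/M, S phase, histone, apoptosis regulator, heat shock, NRF2, metallothionein and respiratory chain genes, and markers of fibroblasts and of leukocytes and endothelium. The comparisons, tests, lists, rule for named genes and all alternatives but 1 were chosen before the data were examined. The exception left out probes with 8 or more bases of alternating G and A and was chosen after seeing the data.

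Named genes were the 10 with the largest rise and the 10 with the largest fall among those past the test with the same sign in every array and an approved symbol. In addition the 4 members with the lowest p of each list with a shift, or with at least 3 members past the test, were named, and the member with the lowest p of other lists. VIM, CDH1, ETS1, ERF, EGR1, CXCL8 and IL6 were always given. This made 153 genes. XIST and Y-linked genes were left out of the named genes and of the tables of single genes.

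The alternatives were no background subtraction, the scanner's processed signals centred on the array median, median centring in place of loess, Aquantile after loess, no filter or a strict filter on dim probes (31217 probes), the authors' values, the 8 arrays fitted singly with the extract pair as a random block and a dye term, all probes, the slide as a block, a trended and robust prior, an added change of at least 1 on the log2 scale, each time fitted alone, and leaving out each replicate column in turn. For uninfected cells they were quantile normalisation of all channels, no filter, the slide as a block, leaving out each extract, and lmscFit on 16 channels. For the lists they were the estimated correlation, no filter, median centring, no background subtraction, the slide as a block and leaving out each replicate.

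The procedure was tested on simulated data of 16383 genes in 20 simulations with 50 changed genes per size. At 24 h and 48 h it recovered 67.1% and 64.4% of changes of 1 on the log2 scale and 96.2% and 95.6% of changes of 2, and of the differences between times 10.4% and 84.7%. False calls made up 5.75%, 4.86% and 4.67% of calls at 24 h, at 48 h and in the difference. Each simulated gene had the same spread at both times, drawn from limma's fitted prior, so a false share near the threshold was built in. The rates need not hold for arrays whose spread differs between the times. A shift of 0.5 in a list of 20 genes was found in 20 of 20 simulations with the preset correlation and in 0 of 20 with the estimated one. Simulated genes were drawn independently of each other, so the preset correlation was not tested for genes that vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and files were read with the R package data.table (version 1.17.8).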

Results

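The transcriptome of End1/E6E7 cells was measured at 24 h and 48 h after infection with Chlamydia trachomatis L2, a bacterium that grows inside a vacuole of its host cell. End1/E6E7 is an epithelial line from the human endocervix, immortalised with papillomavirus genes. RNA of infected cells and RNA of uninfected cells of the same time and replicate were hybridised together on 2-colour oligonucleotide arrays, and each pair of extracts was measured on 2 arrays with the dyes exchanged. There were 2 biological replicates of each state at each time, 8 arrays in all. The comparisons ask which host transcripts were higher or lower in infected cells at each time, whether the response differed between the times, and whether uninfected cells changed over the same interval. The median spot intensity of an array lay between 193 and 392 in Cy3 and between 481 and 926 in Cy5, and between 78.9% and 87.7% of spots in Cy3 and between 80.8% and 87.5% in Cy5 were well above background. No spot was saturated, and the small number of arrays limits the precision. Values are log2 ratios of infected over uninfected cells, given as mean ± SD of n = 2 replicates, with p-values from limma adjusted by the Benjamini-Hochberg method over 16383 genes.

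At 24 h, 62 genes rose and 12 fell in infected cells. The largest rise was that of ANGPTL4, a secreted inhibitor of lipoprotein lipase, at 3.19 ± 0.32 (adjusted p = 0.0230). IFNB1, which encodes interferon beta, rose by 2.49 ± 0.27, IFNL2, an interferon of the lambda type, by 2.30 ± 0.25, and EDN1, the precursor of endothelin-1, by 2.23 ± 0.31. GLB1L3, which resembles beta-galactosidase, rose by 2.23 ± 0.25. The largest falls were those of SLC47A2, a transporter of organic cations, at -2.16 ± 0.34, and of SOX2, a transcription factor of stem and progenitor cells, at -1.94 ± 0.11. ACKR3, a chemokine scavenging receptor, was at -1.63 ± 0.15, TRIM6, a ubiquitin ligase, at -1.45 ± 0.08, F2R, the thrombin receptor, at -1.14 ± 0.18, and LMO1 at -1.07 ± 0.07. PSRC1 and FAM83D, which both act on the mitotic spindle, were at -1.04 ± 0.01 and -0.96 ± 0.11, and SLITRK5 and BBOX1 were both at -0.91, with SDs of 0.01 and 0.06.

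The values of HMBOX1 (2.72 ± 0.37), CD86 (2.64 ± 0.06), IRX5 (2.50 ± 0.24) and CABP7 (2.49 ± 0.42) at 24 h came from probes that hold a GA dinucleotide repeat. Other probes of HMBOX1, CD86 and IRX5, without the repeat, gave 0.20, -0.14 and 0.18, and CABP7 had no other probe. PYGO1, whose probe has no such repeat, rose by 2.21 ± 0.27 on the chosen probe and had 0.02 on its other probe. Of the 21 genes past the test at 24 h with another measured probe, 18 had the same sign on both and 7 differed by over 1.

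The lowest adjusted p at 24 h was 0.0230, 3907 genes had an unadjusted p under 0.05, and 60 of the 74 genes (53 up, 7 down) also changed by at least 1 on the log2 scale. All 74 had the same sign in every array of that time. The count was 2208 (986 up, 1222 down) with the slide, which coincides with the replicate number, as a block and 265 (147 up, 118 down) with the scanner's processed signals. It was 31 (27 up, 4 down) with median centring in place of loess, and 0 with a trended and robust prior, where 3259 genes had an unadjusted p under 0.05. The spread was pooled over both times. Without either 48 h replicate no gene passed at 24 h (2257 and 2260 genes at an unadjusted p under 0.05), while 127 and 4129 passed without 24 h replicate 1 and 2.

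**Figure D1:**
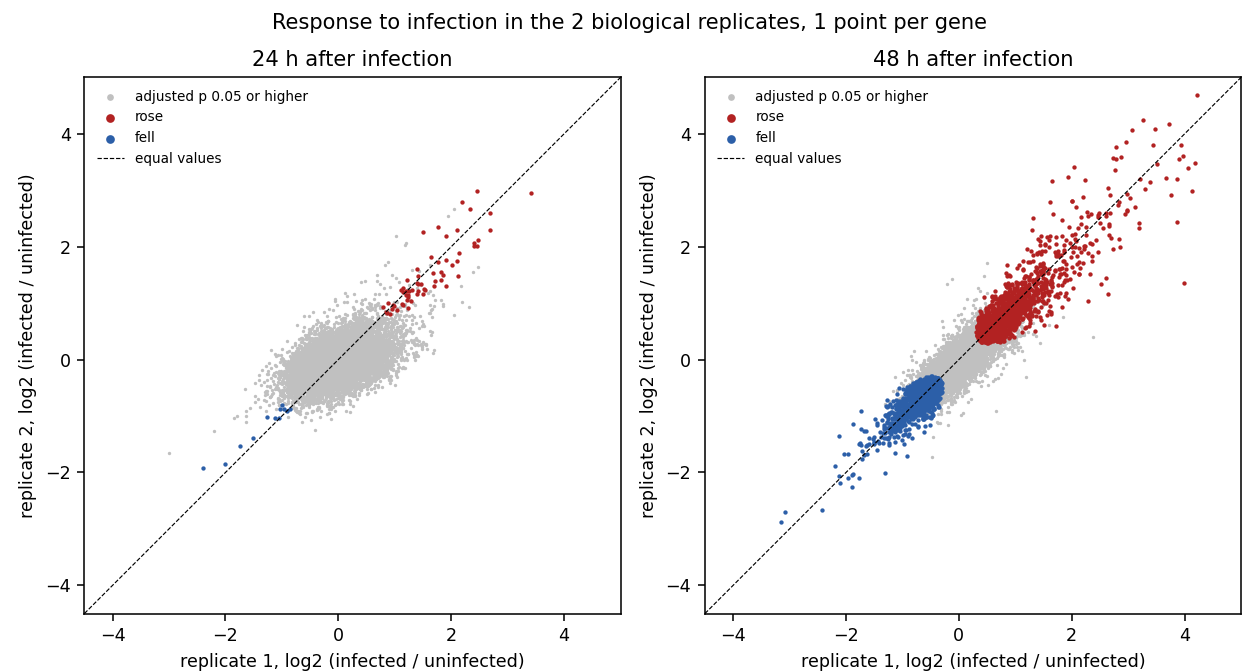
Log2 ratio of infected over uninfected cells in replicate 1 (horizontal axis) and replicate 2 (vertical axis) at 24 h and 48 h, 1 point per gene, with genes that rose in red and genes that fell in blue. The cloud follows the dashed line of equal values more closely at 48 h (Pearson r across genes 0.904) than at 24 h (0.513).

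Inflammatory cytokines and NF-kB target genes were the list with the largest shift at 24 h: 5 of 24 members rose (20 adjusted over the list alone), with a median of 0.89 (0.92 in replicate 1 and 0.76 in replicate 2). CXCL8, the neutrophil chemokine interleukin 8, rose by 2.05 ± 0.21 (adjusted p = 0.0230), IL6 by 1.67 ± 0.25 (0.0328), CXCL3 by 1.23 ± 0.03 (0.0284) and CXCL2 by 1.18 ± 0.07 (0.0296). Of the immediate-early and ERK feedback genes, 3 of 20 rose (18 adjusted over the list alone), with a median of 0.75: DUSP1, a MAP kinase phosphatase, by 1.61 ± 0.43, FOS, a subunit of AP-1, by 1.50 ± 0.15, and DUSP5 by 1.17 ± 0.03. EGR1 was at 0.77 ± 0.32 (adjusted p = 0.0780) and ATF3 at 0.88 ± 0.18 (0.0641). Of the TGF-beta and YAP target genes, PMEPA1 rose by 0.96 ± 0.12, 1 of 14 (7 adjusted over the list alone), and the list's median was 0.39. By camera with a preset correlation the adjusted p was 3.86e-15 for the cytokines, 5.09e-12 for the immediate-early genes and 0.00170 for the TGF-beta and YAP targets. These became adjusted p = 0.182, 0.182 and 0.481 with an estimated correlation.

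Of the type I interferon-stimulated genes, 3 of 23 rose at 24 h (10 adjusted over the list alone): IFNB1, CXCL11 by 2.06 ± 0.42 and CXCL10 by 1.88 ± 0.55. IFNB1 encodes an interferon itself, but it was on this list and enters its counts, median and test at both times. RSAD2, an antiviral enzyme, was at 0.87 ± 0.10 (adjusted p = 0.0684), and the list's median was 0.37 (0.55 and 0.23 in the replicates; camera adjusted p = 3.80e-08, and adjusted p = 0.310 with an estimated correlation). Median centring brought that median to 0.02 (adjusted p = 0.211). Of the hypoxia and glycolysis genes, 3 of 21 rose (13 adjusted over the list alone) around a median of 0.66: DDIT4, an inhibitor of mTORC1, by 1.28 ± 0.17, PFKFB4, a kinase that sets the rate of glycolysis, by 1.17 ± 0.08, and HK2, a hexokinase, by 0.92 ± 0.04. NDRG1 was at 0.91 ± 0.17 (adjusted p = 0.0535). The camera adjusted p was 1.11e-08 (adjusted p = 0.310 with an estimated correlation).

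The G2/M cell cycle genes lay below 0 at 24 h in all 20 members, with a median of -0.62 (-0.56 and -0.59 in the replicates). None of the 20 passed over all genes and 18 did when adjusted over the list alone. CCNB1, the cyclin of mitotic entry, was at -0.80 ± 0.17 (adjusted p = 0.0641), CCNB2 at -0.78 ± 0.02 (0.0549), TOP2A at -0.75 ± 0.06 (0.0549) and BUB1 at -0.71 ± 0.07 (0.0641). A second probe of CCNB2 gave 1.05. The list's camera adjusted p was 1.18e-13 (adjusted p = 0.225 with an estimated correlation).

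NRF2 oxidative stress genes had a median of -0.22 at 24 h, with 0 of 15 past the test (2 down adjusted over the list alone). GCLM, a subunit of the enzyme that starts glutathione synthesis, was at -0.55 ± 0.03, AKR1B10 at -1.39 ± 0.56, AKR1C1 at -0.94 ± 0.75 and NQO1 at -0.51 ± 0.48. Respiratory chain genes had a median of -0.23 and cholesterol synthesis and uptake genes one of -0.21, with no member past the test over all genes or adjusted over the list alone. ATP5PB was at -0.50 ± 0.06 and ATP5F1A at -0.37 ± 0.10, subunits of the ATP synthase, COX5B was at -0.28 ± 0.03, COX7B at -0.40 ± 0.33, and MVK, an enzyme of the mevalonate pathway, at -0.52 ± 0.25. The camera adjusted p of the 3 lists was 0.00168, 0.00465 and 0.0106 in this order, and adjusted p = 0.524, 0.524 and 0.481 with an estimated correlation. Without 24 h replicate 1 the medians were -0.12, -0.04 and -0.06, and the adjusted p 0.162, 0.299 and 0.174.

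Epithelial junction and keratin genes had a median of 0.20 at 24 h (camera adjusted p = 0.00189, and adjusted p = 0.514 with an estimated correlation), and 1 of 22 rose (2 up and 1 down adjusted over the list alone). That member was CLDN4, a tight junction claudin, at 1.61 ± 0.10 (adjusted p = 0.0230). OVOL1 was at 0.83 ± 0.23, OCLN at 0.50 ± 0.07 and GRHL2, a transcription factor of epithelial cells, at -0.54 ± 0.25. The list's direction turned with median centring, to a median of -0.10. ETS family transcription factors had a median of 0.12, with 0 of 18 past the test over all genes or adjusted over the list alone, and a camera adjusted p of 0.0273 (adjusted p = 0.481 with an estimated correlation). ETS1 was at 0.74 ± 0.22 (adjusted p = 0.0882), ETV6 at 0.46 ± 0.16, FLI1 at 0.39 ± 0.11 and ETV5 at 0.33 ± 0.09. The ETS call was lost without 24 h replicate 2 (adjusted p = 0.269) and with median centring (0.383).

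The other lists did not shift at 24 h, and none of their members passed over all genes. Mesenchymal genes of EMT had a median of 0.04 (camera adjusted p = 0.750), with TNC at 0.68 ± 0.26. Medians and camera adjusted p were 0.16 and 0.112 for antigen presentation (TAP1 0.63 ± 0.26), 0.15 and 0.0831 for ER chaperones (DNAJC3 0.35 ± 0.11), 0.06 and 0.422 for the ATF4 response (STC2 0.98 ± 0.09), and 0.16 and 0.128 for S phase (CCNE1 0.54 ± 0.11). They were 0.14 and 0.131 for histones (H2BC8 0.53 ± 0.03), 0.09 and 0.274 for BCL2 and IAP family apoptosis regulators (BIRC3 0.72 ± 0.22), -0.13 and 0.131 for heat shock (HSPB1 -0.39 ± 0.20), and -0.10 and 0.279 for metallothioneins (MT1F -0.19 ± 0.50). The p53 targets had a median of -0.04 and a mean of 0.11, with test direction up (adjusted p = 0.775) and PLK3 at 1.38 ± 0.28 (0.0525). Markers of other cell types stayed near 0, at -0.03 for fibroblasts (adjusted p = 0.815; THY1 0.15 ± 0.14) and 0.04 for leukocytes and endothelium (0.278; VWF -0.44 ± 0.03). Adjusted over the list alone, the members past the test were 2 mesenchymal genes, 1 ATF4 target, 3 S phase genes and 3 histones (all up), 6 p53 targets up and 4 down, 5 apoptosis regulators up and 2 down, and 1 leukocyte or endothelial marker each way.

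At 48 h, 1528 of the 16383 genes rose and 1401 fell in infected cells, and the counts of list members below are to be read against these shares. MMP1, an interstitial collagenase, rose most, by 4.46 ± 0.34 (adjusted p = 0.00208; probe on chromosome 11 from 102660697 to 102660756 of hg19). It was followed by G0S2, an inhibitor of triglyceride lipase, at 3.95 ± 0.31, CXCL8 at 3.87 ± 0.09 and EDN1 at 3.84 ± 0.49. IL23A, a subunit of interleukin 23, was at 3.79 ± 0.25, IL6 at 3.73 ± 0.25, SERPINB2, an inhibitor of plasminogen activators, at 3.73 ± 0.47, and CCL20, a chemokine of dendritic cells and lymphocytes, at 3.62 ± 0.25. The probes of CD86 and HMBOX1 with a GA repeat read 3.78 ± 0.43 and 3.75 ± 0.69, and the other probes of these genes -0.13 and 0.31. The largest falls were SLC47A2 at -3.02 ± 0.19, VAV3, a guanine nucleotide exchange factor, at -2.89 ± 0.27, SOX2 at -2.54 ± 0.18 and CCN5, a matricellular protein, at -2.15 ± 0.06. FBXO32, a ubiquitin ligase subunit of muscle atrophy, was at -2.09 ± 0.04, GPNMB at -2.07 ± 0.27, DOCK8 at -2.04 ± 0.10, TMT1A at -2.03 ± 0.22, TRIM6 at -1.97 ± 0.10 and NANOS1 at -1.95 ± 0.11. Second probes gave -0.96 for VAV3, -0.39 for DOCK8, -1.27 for SOX2, -1.43 for TMT1A and -2.02 for TRIM6.

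The lowest adjusted p at 48 h was 0.00208, 6270 genes had an unadjusted p under 0.05, and 643 genes (483 up, 160 down) also changed by at least 1. Of the 1239 called genes with another probe, 1141 (92.1%) had the same sign on both. The count was 5639 (2834 up, 2805 down) with the slide as a block and 1507 (752 up, 755 down) with a trended and robust prior. The share of called genes that rose was 52.2%, against 30.8% (728 up, 1633 down) with median centring. Without 48 h replicate 1 or 2 the count was 63 or 57, and without 24 h replicate 1 or 2 it was 7140 or 7137, since the pooled spread then rested on a single time.

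Inflammatory cytokines and NF-kB targets had a median of 1.86 at 48 h, and 21 of 24 rose, over all genes and adjusted over the list alone. CXCL3 rose by 2.52 ± 0.08 and CXCL2 by 2.30 ± 0.07, beside CXCL8, IL6 and CCL20. Of the immediate-early and ERK feedback genes, 18 of 20 rose (19 adjusted over the list alone) around a median of 1.65: DUSP1 by 3.27 ± 0.16, FOS by 3.20 ± 0.01, ATF3 by 2.19 ± 0.17, DUSP5 by 1.89 ± 0.23 and EGR1 by 1.56 ± 0.13 (adjusted p = 0.00777). Of the TGF-beta and YAP targets, 9 of 14 rose (10 adjusted over the list alone) around a median of 0.63: INHBA, which encodes the activin subunit beta A, by 2.91 ± 0.30, PMEPA1 by 1.94 ± 0.11, SKIL by 1.29 ± 0.07 and CCN2 by 1.25 ± 0.35. The camera adjusted p was 6.57e-16, 5.57e-14 and 9.01e-06 for the 3 lists, and adjusted p = 0.154, 0.154 and 0.508 with an estimated correlation.

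**Figure D2:**
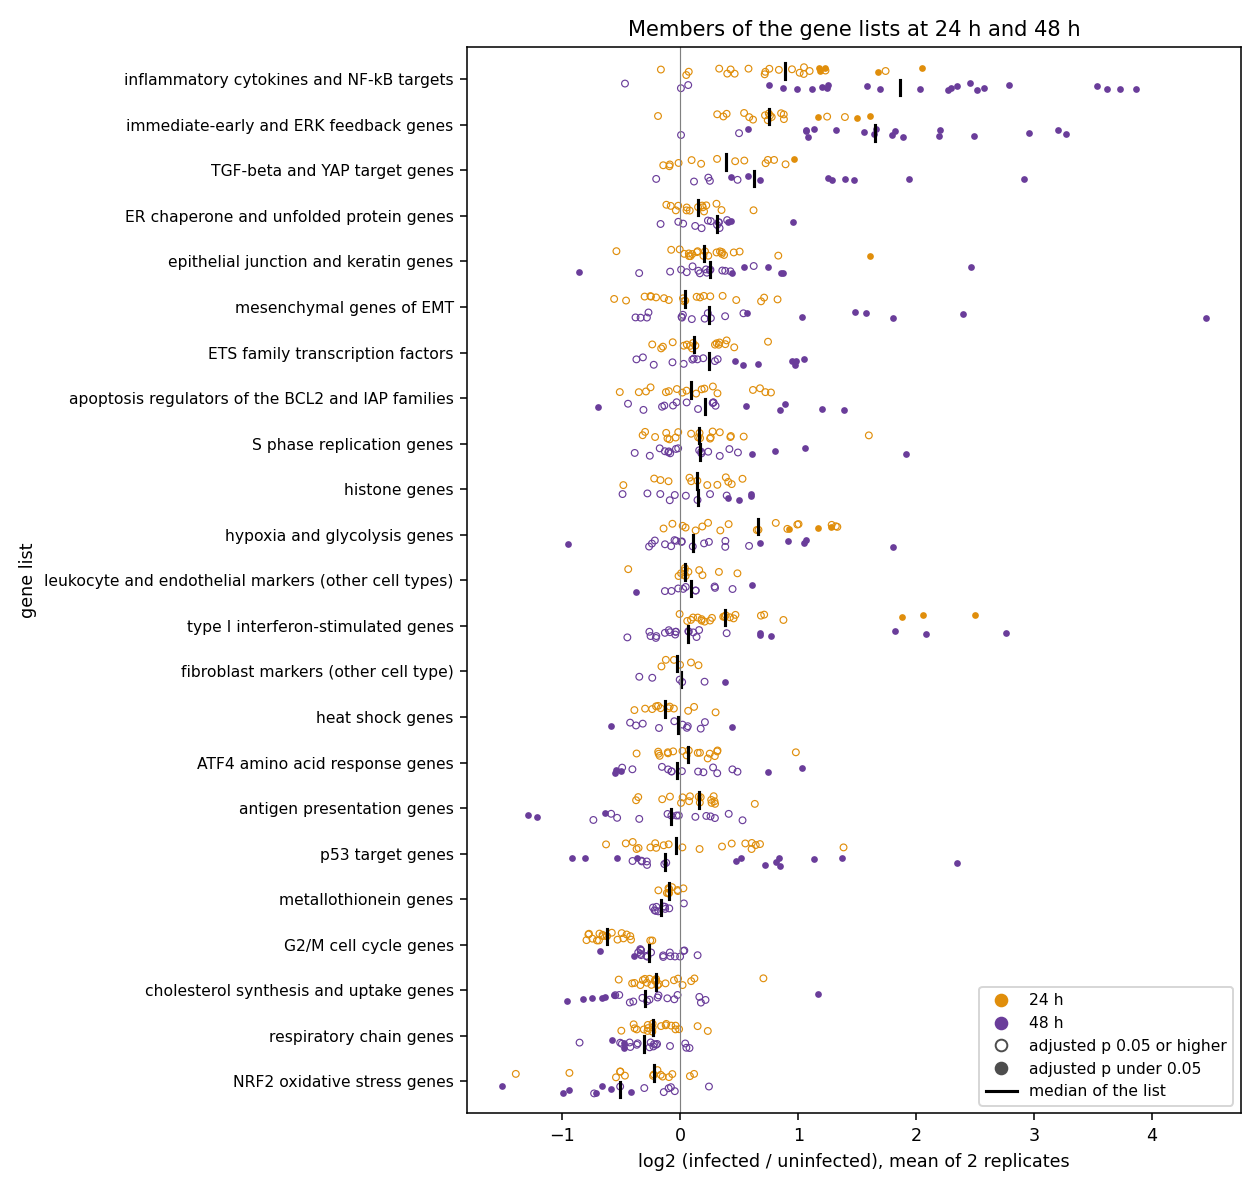
Log2 ratio of infected over uninfected cells (horizontal axis, mean of 2 replicates) of each member of the 23 gene lists (vertical axis), at 24 h in orange and 48 h in purple, with filled points for members past the test and a black bar at the list's median. The inflammatory cytokines lie furthest to the right, with medians of 0.89 and 1.86, and the NRF2 genes furthest to the left at 48 h, with a median of -0.51.

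Genes of the epithelial to mesenchymal transition were examined because the line is epithelial. VIM, which encodes the intermediate filament vimentin, rose by 1.03 ± 0.34 at 48 h (adjusted p = 0.0162) and was at -0.56 ± 0.07 at 24 h (0.112), and its second probe gave 0.63 and -0.62. SNAI1, a repressor of E-cadherin, rose by 1.80 ± 0.08 at 48 h, TNC, a matrix glycoprotein, by 1.57 ± 0.08 and ITGA5, a fibronectin receptor subunit, by 1.48 ± 0.43. In all, 7 of 20 mesenchymal genes rose, over all genes and adjusted over the list alone, with a median of 0.25 and a mean of 0.69 (camera adjusted p = 0.00682, and adjusted p = 0.508 with an estimated correlation). CDH1, which encodes E-cadherin, was at 0.62 ± 0.57 at 48 h (adjusted p = 0.161) and 0.35 ± 0.56 at 24 h (0.471; probe on chromosome 16 from 68869214 to 68869273 of hg19). CDH1 at 48 h passed with the slide as a block (adjusted p = 0.00479). It turned to -0.056 at 48 h and -0.071 at 24 h with median centring, and to -0.046 at 24 h without replicate 1 of that time. Among the epithelial junction and keratin genes, 6 of 22 rose and 1 fell at 48 h (7 and 1 adjusted over the list alone): CLDN4 rose by 2.46 ± 0.07, KRT18 by 0.87 ± 0.24 and OVOL1 by 0.86 ± 0.21, and GRHL2 fell, at -0.86 ± 0.03. Their median was 0.25 (camera adjusted p = 0.00418, and adjusted p = 0.508 with an estimated correlation). That median turned to -0.23 with median centring, and the call was lost without 48 h replicate 1 (median 0.13, adjusted p = 0.160).

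Of the ETS family transcription factors, 7 of 18 rose at 48 h (8 up and 1 down adjusted over the list alone). ETS1 rose by 1.05 ± 0.32 (adjusted p = 0.0183), FLI1 by 0.98 ± 0.23, ETV4 by 0.97 ± 0.06 and ETV5 by 0.95 ± 0.02, the last a target of ERK signalling. ERF, an ETS repressor, was at 0.03 ± 0.02 (adjusted p = 0.844) and 0.11 ± 0.12 at 24 h (0.505; probe on chromosome 19 from 42752246 to 42752305 of hg19). ERF turned to -0.14 at 48 h and -0.072 at 24 h with median centring, and to -0.026 at 48 h with the scanner's processed signals. The list's median was 0.24 (camera adjusted p = 0.0104, and adjusted p = 0.508 with an estimated correlation), and the call was lost with median centring (0.232).

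Of the NRF2 oxidative stress genes, 7 of 15 fell at 48 h (9 adjusted over the list alone), with a median of -0.51 (-0.60 and -0.34 in the replicates). AKR1B10 was at -1.51 ± 0.52, GCLC, the catalytic subunit of glutamate-cysteine ligase, at -0.72 ± 0.17, and GCLM at -0.59 ± 0.07. Of the respiratory chain genes, 3 of 20 fell, over all genes and adjusted over the list alone, around a median of -0.31: ATP5F1A at -0.58 ± 0.12, ATP5PB at -0.48 ± 0.13 and COX5B at -0.48 ± 0.03. Of the cholesterol synthesis and uptake genes, 6 of 22 fell and 1 rose (8 and 1 adjusted over the list alone) around a median of -0.30. MVK, at -0.96 ± 0.01, IDI1, at -0.75 ± 0.02 and FDFT1, at -0.66 ± 0.09, enzymes of sterol synthesis, were among those that fell. The camera adjusted p was 0.000629, 0.000404 and 0.00512 for the 3 lists, and adjusted p = 0.508 for each with an estimated correlation.

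Of the G2/M genes, 2 of 20 fell at 48 h (1 adjusted over the list alone): KIF20A, at -0.68 ± 0.11, and TOP2A, at -0.39 ± 0.03. That count is near the share of all genes that fell, 1401 of 16383. The G2/M list's median was -0.26 (camera adjusted p = 0.00325, and adjusted p = 0.508 with an estimated correlation). Of the S phase genes, 4 of 20 rose (4 up and 1 down adjusted over the list alone): E2F1, a transcription factor of S phase entry, by 1.91 ± 0.57, CCNE1 by 1.05 ± 0.01, CDC6 by 0.80 ± 0.11 and CDC45 by 0.61 ± 0.03. The S phase list had a median of 0.17 and no shift (camera adjusted p = 0.201). Of the ER chaperone genes, 3 of 15 rose (4 adjusted over the list alone) around a median of 0.31: XBP1 by 0.96 ± 0.44, DNAJC3 by 0.43 ± 0.04 and DNAJB11 by 0.40 ± 0.02. Their camera adjusted p was 0.00643 (adjusted p = 0.508 with an estimated correlation), the call was lost without 48 h replicate 1 (0.0734), and the median turned to -0.23 with median centring, as did DNAJB11, to -0.064.

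Of the type I interferon-stimulated genes, 6 of 23 rose at 48 h (6 up and 1 down adjusted over the list alone). IFNB1 rose by 2.76 ± 0.61, CXCL11 by 2.09 ± 0.02, CXCL10 by 1.82 ± 0.08 and OASL by 0.68 ± 0.02, while the list's median was 0.07 (camera adjusted p = 0.288). Antigen presentation genes had a median of -0.08 and no shift of the list (0.288). Of these genes 3 of 17 fell (2 up and 4 down adjusted over the list alone): HLA-DRA, a chain of an HLA class II molecule, at -1.29 ± 0.23, CIITA, the transactivator of class II genes, at -1.21 ± 0.07, and PSMB10, an immunoproteasome subunit, at -0.64 ± 0.07. Other probes of CIITA gave -0.40. Of the hypoxia and glycolysis genes, 5 of 21 rose and 1 fell, over all genes and adjusted over the list alone, around a median of 0.11 (0.201). VEGFA, the vascular growth factor, rose by 1.80 ± 0.11, ENO2 by 1.07 ± 0.02, DDIT4 by 1.05 ± 0.00 and NDRG1 by 0.91 ± 0.04. PFKFB4 was at 0.01 ± 0.13 and HK2 at 0.24 ± 0.15, both named after their values were seen because they had risen at 24 h.

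Of the p53 targets, 9 of 20 rose and 4 fell at 48 h (9 and 7 adjusted over the list alone). PLK3 rose by 2.34 ± 0.27 and CDKN1A, an inhibitor of cyclin-dependent kinases, by 1.14 ± 0.07, while SESN1 was at -0.91 ± 0.04 and TP53INP1 at -0.81 ± 0.04. The list's median was -0.13 and its mean 0.23, with test direction up (camera adjusted p = 0.824). Of the BCL2 and IAP family apoptosis regulators, 5 of 18 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.21, 0.136). PMAIP1 rose by 1.38 ± 0.28 and BBC3 by 0.84 ± 0.29, both BH3-only death activators, and BIRC3, an inhibitor of cell death, by 1.20 ± 0.05. HRK fell, at -0.70 ± 0.05, with 0.35 on its other probe. Of the ATF4 response genes, 2 of 18 rose and 3 fell (3 and 3 adjusted over the list alone): CEBPB rose by 1.03 ± 0.01 and STC2 by 0.74 ± 0.26, and CTH and PSAT1, both at -0.55, were among those that fell. Their median was -0.03 and their mean 0.04, with test direction up (adjusted p = 0.918).

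The remaining lists did not shift at 48 h. Of 13 histone genes, H2BC8, H2BC11, H2AC8 and H4C8 rose, by 0.60 ± 0.15, 0.60 ± 0.15, 0.49 ± 0.04 and 0.40 ± 0.05, over all genes and adjusted over the list alone (median 0.15, camera adjusted p = 0.229). Of 12 heat shock genes, 1 rose and 1, HSPB1, fell, at -0.59 ± 0.09 (1 up and 4 down adjusted over the list alone; median -0.02, 0.459). No metallothionein passed, over all genes or adjusted over the list alone (median -0.16, 0.116; MT1E -0.21 ± 0.08). Among markers of other cell types, COL1A1 rose by 0.38 ± 0.07, 1 of 6 fibroblast markers in both adjustments (median 0.01 with test direction down, 0.984). Of the leukocyte and endothelial markers, CD68 rose by 0.61 ± 0.02 and 1 of 12 fell (2 and 1 adjusted over the list alone; median 0.09, 0.288).

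No gene passed the limma test of the difference between 48 h and 24 h, where 1210 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.140, that of MMP1, with a difference of 3.98 ± 0.53. CCL20 had a difference of 2.39 ± 0.05 (adjusted p = 0.192), IL6 of 2.06 ± 0.00 (0.208), INHBA of 2.02 ± 0.09 (0.242), CXCL8 of 1.82 ± 0.30 (0.192), FOS of 1.70 ± 0.16 (0.192) and VIM of 1.59 ± 0.41 (0.242). PFKFB4 and BNIP3, a mitophagy receptor, had differences of -1.16 ± 0.05 (0.242) and -1.41 ± 0.31 (0.260). Here and below, the SD of a difference is that of the differences between same-numbered replicates. The limma test did not pair the replicates, so these SDs are not the spread behind its p-values. With the slide as a block 127 genes passed (118 higher and 9 lower at 48 h). With the 8 arrays fitted singly 223 passed (204 and 19), and with the scanner's processed signals 1. The fit of single arrays took the ratios as red over green, with a correlation of -0.618 between dye-swapped arrays. On that scale a negative value raises the standard errors of the infection effect.

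As lists, 7 of the 23 lay higher at 48 h than at 24 h by camera and 6 lower, although no member passed over all genes. Medians of the difference were 1.11 for inflammatory cytokines (17 of 24 members past the test adjusted over the list alone), 0.78 for immediate-early genes (13 of 20), 0.52 for TGF-beta and YAP targets (4 of 14), 0.38 for G2/M genes (0 of 20) and 0.27 for mesenchymal genes (6 of 20). They were -0.37 for hypoxia and glycolysis genes (3 of 21, down), -0.20 for interferon-stimulated genes (0 of 23) and -0.19 for antigen presentation genes (2 of 17, down). The camera adjusted p was 6.94e-24, 1.20e-20, 9.19e-08, 9.58e-11 and 1.72e-06 for the lists shifted up and 1.49e-08, 1.01e-05 and 1.33e-05 for those shifted down. With an estimated correlation these became adjusted p = 0.104, 0.104, 0.271, 0.194 and 0.194, and 0.262, 0.271 and 0.194.

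The other 5 called shifts had higher adjusted p. The medians were 0.11 for ETS factors (2 of 18 up adjusted over the list alone), 0.11 for ER chaperones, -0.07 for cholesterol genes, -0.22 for NRF2 genes and -0.14 for respiratory chain genes, with no member past the test adjusted over the list alone in the last 4. ETV4, at 0.68 ± 0.21, SDF2L1, at 0.34 ± 0.03, IDI1, at -0.51 ± 0.29, GCLC, at -0.55 ± 0.28, and UQCRC2, at -0.17 ± 0.02, were among the members with the lowest p. The camera adjusted p was 0.0363, 0.0317, 0.0393, 0.0281 and 0.00799, and adjusted p = 0.466, 0.429, 0.466, 0.625 and 0.625 with an estimated correlation. The ETS call was lost with the slide as a block (0.0698), and each of the 5 was lost without at least 1 replicate, at adjusted p of 0.382, 0.505, 0.425, 0.831 and 0.809 without the replicate that mattered most. The NRF2 median then turned to 0.056 (without 24 h replicate 2).

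The lists not shifted between the times were the epithelial genes (median difference 0.08, camera adjusted p = 0.160), the apoptosis regulators (0.16, 0.0645), the ATF4 response (-0.08, 0.347), the p53 targets (0.09, 0.367), the S phase genes (0.06, 0.367) and the histones (0.05, 0.797). The same held for heat shock genes (0.00, 0.797), metallothioneins (-0.10, 0.231), fibroblast markers (0.02, 0.844) and leukocyte and endothelial markers (0.04, 0.606). CLDN4, the only member of these lists past the test adjusted over the list alone, had a difference of 0.85 ± 0.04.

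**Figure D3:**
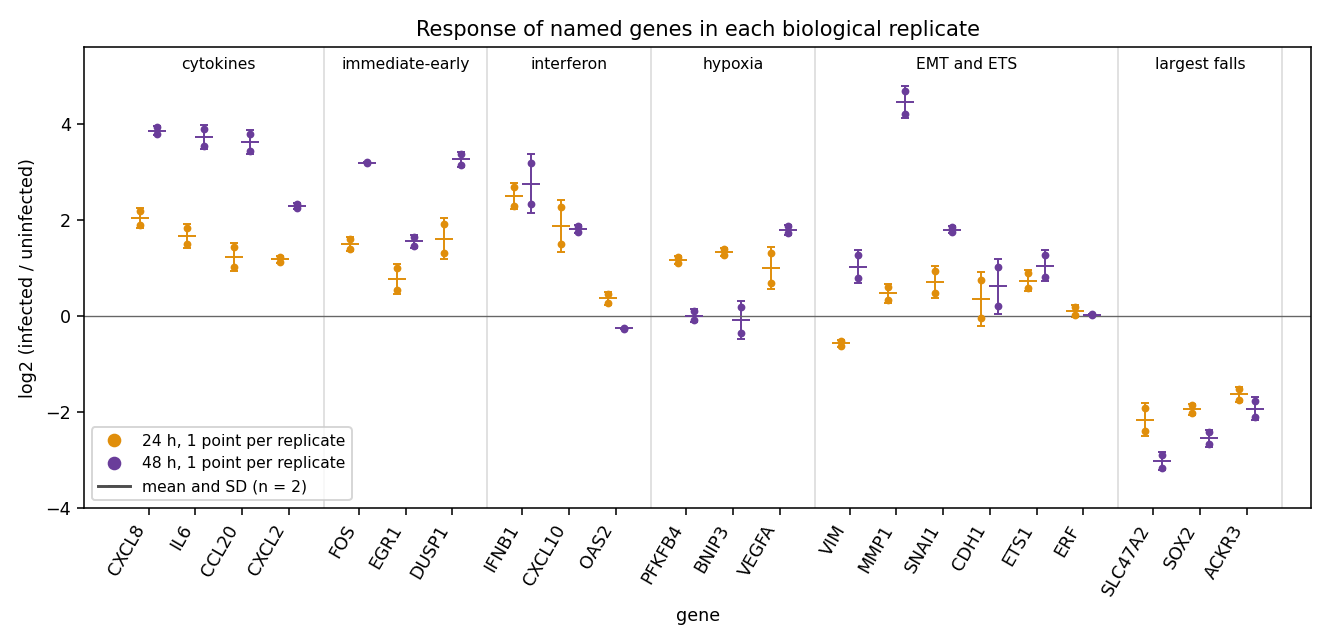
Log2 ratio of infected over uninfected cells (vertical axis) of named genes (horizontal axis) at 24 h in orange and 48 h in purple, 1 point per biological replicate with the mean and SD (n = 2). CXCL8 moved from 2.05 to 3.87 and MMP1 from 0.47 to 4.46, while PFKFB4 lay at 1.17 and 0.01 and ERF near 0 at both times.

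The genes called at 24 h were nearly all called at 48 h as well: 60 of the 62 that rose and all 12 that fell. The times have separate uninfected extracts, so no control was shared, but both tests used the same pooled spread and the same slides. Of the genes that rose at 48 h, 95.7% were above 0 at 24 h in replicate 1 and 91.6% in replicate 2, with medians of 0.50 and 0.29 against 0.77 at 48 h. Of those that fell, 98.6% and 94.9% were below 0, with medians of -0.50 and -0.31 against -0.61. Across the 16383 genes, which are not independent replicates, the mean responses at the 2 times had a Pearson r of 0.842 and a Spearman rho of 0.816. Taken between different replicates, r was 0.753 (24 h of replicate 1 with 48 h of replicate 2) and 0.559 (24 h of replicate 2 with 48 h of replicate 1).

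In uninfected cells no gene passed the limma test of 48 h against 24 h, where 1207 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.326. This comparison lies between arrays and not within them. Among the lists, the medians furthest from 0 were those of the G2/M genes, at -0.66, cholesterol genes, at 0.47, metallothioneins, at 0.44, and TGF-beta and YAP targets, at -0.36. No list was tested in uninfected cells. With the slide as a block 4 genes passed (1 up, 3 down), and a fit of all 16 channels with an estimated intraspot correlation, which counts channels of the same extract as replicates, called 1164 (551 up, 613 down).

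Probes that hold a GA dinucleotide repeat had higher ratios than the rest of the array. The 94 measured probes with 8 or more bases of alternating G and A had a median log2 ratio of 0.25 at 24 h and 0.36 at 48 h, against 0.01 and 0.00 for the 34121 other probes, and 22.3% of them exceeded 1 at 48 h, against 2.89%. The value grew with the length of the stretch: the median at 48 h was 0.24 over 80 probes with a stretch of 8 bases, 1.80 over 7 probes with 10 bases and 3.61 over 7 probes with 12 or more. Probes with 8 or more bases of alternating C and A, G and T, or C and T had medians of 0.20, 0.13 and 0.10 at 48 h, and 5.48%, 2.15% and 3.95% of them exceeded 1. Without these probes 58 genes passed at 24 h (49 up, 9 down) and 2908 at 48 h, and 5 of the genes that rose at 24 h and 21 of those that rose at 48 h were measured by them.

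**Figure D4:**
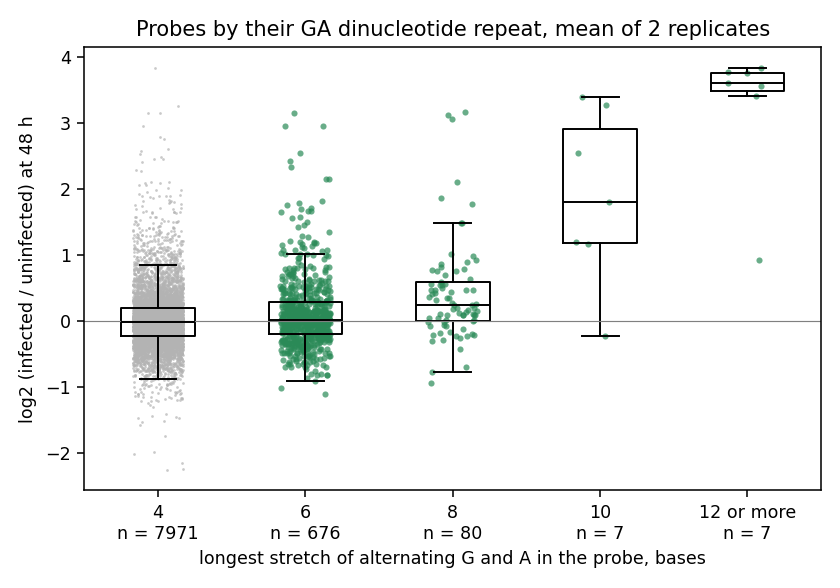
Log2 ratio of infected over uninfected cells at 48 h (vertical axis, mean of 2 replicates) of single probes by the length in bases of their longest stretch of alternating G and A (horizontal axis), with boxes from the lower to the upper quartile around the median and whiskers to the furthest probe within 1.5 box lengths. The medians are -0.01, 0.02, 0.24, 1.80 and 3.61 from 4 bases to 12 or more.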

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

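Of the tests below, those on other probes of the same genes, on bacterial RNA, on array noise, on the same fraction in every list, on signal range and on a delay were chosen after the result was seen.

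The response of 13 lists differed between 48 h and 24 h by camera with a preset correlation, in which the difference itself was tested. Inflammatory cytokines and NF-kB targets (adjusted p = 6.94e-24, median difference 1.11), immediate-early genes (1.20e-20, 0.78), G2/M genes (9.58e-11, 0.38), TGF-beta and YAP targets (9.19e-08, 0.52) and mesenchymal genes (1.72e-06, 0.27) lay higher at 48 h, as did ER chaperones (0.0317, 0.11) and ETS factors (0.0363, 0.11). Hypoxia and glycolysis genes (1.49e-08, -0.37), interferon-stimulated genes (1.01e-05, -0.20), antigen presentation genes (1.33e-05, -0.19), respiratory chain genes (0.00799, -0.14), NRF2 genes (0.0281, -0.22) and cholesterol genes (0.0393, -0.07) lay lower. With an estimated correlation none of the 13 passed (lowest adjusted p = 0.104). In uninfected cells the median at 48 h against 24 h had the opposite sign in 12 of these 13 lists. It was -0.66 for G2/M genes, of which all 20 had higher ratios at 48 h, -0.36 for TGF-beta and YAP targets, 0.47 for cholesterol genes, 0.23 for hypoxia genes, 0.19 for antigen presentation genes, 0.18 for respiratory chain genes and 0.16 for NRF2 genes. Uninfected values enter the difference with a reversed sign. No gene passed in uninfected cells and no list was tested there, so how far a moving reference made these differences stays open.

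Among the 4 arrays of 24 h, the array of replicate 1 with infected cells in Cy3 had a median Cy3 signal of 195, far below the others at 392, 379 and 377. At 48 h the arrays with infected cells in Cy3 had 235 and 193, so a low Cy3 signal was not peculiar to this array. Within each dye, infected cells had the lower median signal in every extract pair. The gap was smallest in 24 h replicate 2, at 377 against 379 in Cy3 and 695 against 732 in Cy5. The flagged array was the only 1 found far from the rest in 10 groups of 4 arrays, and chance marks about 1 in 20 groups. Each group held both dye orders, so the flag did not separate dye order from a far array.

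Probes with a GA dinucleotide repeat had a median of 0.36 at 48 h, higher than purine-rich probes without the repeat, whose median was -0.016 (quartiles -0.25 and 0.22 over 3445 probes), so purine content alone would not raise them. In 44 genes with both kinds of probe the other probes had a median of 0.028 (quartiles -0.14 and 0.27) against 0.46 for the repeat probes. In the 17 genes whose repeat probe was raised these medians were 0.14 and 1.20. The 17 were picked by their high repeat probe, so part of that gap was built in. Probes with 8 or more bases of alternating C and A lay at 0.20, and 5.48% of them exceeded 1. GA probes whose longest stretch was 8 bases lay at 0.24, with 11.25% over 1. The longer GA stretches had the highest medians, but the other repeats were not split by length. Hybridisation through the repeat, and not through the transcripts of genes such as CD86, HMBOX1 and IRX5, is a candidate explanation. Bacterial RNA in the infected extracts cannot be told apart from host RNA with such a repeat: the smaller of the replicates' median differences between 48 h and 24 h was 0.13, which either source would give, and no chlamydial genome was at hand.

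The 24 h replicates had a Pearson r of 0.513 across genes and the 48 h replicates one of 0.904, and the SD of the log2 ratios was 0.41 and 0.29 in 24 h replicates 1 and 2. Noise in replicate 2 as the whole cause is argued against, since the difference between the 24 h replicates had an r of 0.364 with the 48 h response of replicate 2. The dye-swapped arrays of 24 h replicate 2 had an r of only 0.0926 (0.546 in replicate 1). A smaller response and dye effects of probes, which cancel in the averaged columns, also lower that r, so it does not measure noise alone. Noise as a part of the cause stays open. Among genes called at 48 h, the 24 h median of replicate 2 was 0.588 times that of replicate 1 for genes that rose and 0.617 times for genes that fell, a ratio of 1.05 between these, which is what the same fraction for every gene would give in this planned test. As the whole cause that fraction is argued against only by the later test of 9 lists with a shift in replicate 1, where members left it with both quartiles in 3: G2/M genes (-0.56 and -0.59 in replicates 1 and 2) and cytokines (0.92 and 0.76) kept more, and NRF2 genes (-0.32 and -0.12) less. The same fraction with noise added and a response unequal between lists both stay open, as slide and replicate coincide and whether infection itself differed was not tested. In 24 h replicate 2 the median signals of infected and uninfected cells also lay closest, and whether this bears on the response was not tested.

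IFNB1 and CXCL10 rose at both times, while the 17 interferon-stimulated genes not called up at 48 h had a median of 0.25 at 24 h and -0.04 at 48 h. All of them (100%) were well above background and unsaturated in all 16 channel measurements, which argues against signals too dim or too bright. Of 504 genes at least as bright as their median, 27 rose by 1 or more, so some rises were measurable at that level. Brightness was averaged over all arrays, infected cells included, and whether ratios of bright probes were compressed was not tested. The 95% interval reached a doubling in 5.88% of the 17 members. Over all 22 listed genes but IFNB1, the median change from 24 h to 48 h was -0.26 and -0.30 in the replicates (quartiles of the mean -0.43 and -0.031), which argues against a delay of that length and leaves a longer one open. The 17 members not called up had a median log2 intensity of 15.5 over all arrays. With median ratios of 0.25 and -0.04 they were bright in uninfected cells too. These data cannot tell a limited response to the interferon expressed from a level that was high without infection. Such a limited response may be considered as a biological hypothesis, found and examined on the same data, and no biological explanation was tested.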

How the results depend on the processing

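All alternatives were planned except leaving out GA repeat probes, which was chosen after the result was seen.

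At 24 h the count of 74 became 75 without background subtraction, 74 with Aquantile, 107 without a filter, 71 with a strict filter, 107 with the authors' values and 71 with all probes. At 48 h 2929 became 3043, 2926, 3041, 2766, 3031 and 3493. Without GA repeat probes the counts were 58 and 2908, and CD86 turned to -0.14 and -0.13, the value of its other probe. The scanner's processed signals gave 265 genes at 24 h and 1 in the difference, and ERF at 48 h turned to -0.026. Median centring gave 31 at 24 h. It also moved the median of all genes to -0.16 at 24 h and -0.13 at 48 h, and turned the medians of epithelial genes to -0.10 and -0.23 (adjusted p = 0.639 and 0.252) and of ER chaperones to -0.23 at 48 h (0.364). For the ER chaperones' difference the test turned down while the median stayed at 0.063 (0.930). CDH1 turned to -0.071 and -0.056, ERF to -0.072 and -0.14 and DNAJB11 at 48 h to -0.064. The cause of these changes was not tested.

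The slide as a block gave 2208, 5639 and 127 genes at 24 h, at 48 h and in the difference, with all 74 and all 2929 among them, and the 8 arrays fitted singly gave 1987, 5294 and 223. That fit took the ratios as red over green, with a correlation of -0.618 between dye-swapped arrays. On that scale a negative value raises the standard errors of the infection effect. A trended and robust prior gave 0 at 24 h (limma, 3259 genes at an unadjusted p under 0.05) and 1507 at 48 h. Each time alone gave 0 at 24 h (2257 genes at an unadjusted p under 0.05) and 7140 at 48 h, which follows from the spread no longer being pooled over times that differ in it. A change of at least 1 left 643 at 48 h by construction. Leaving out 1 replicate, with the lone sample assumed to vary like the other time, gave 0 to 4129 at 24 h, 57 to 7140 at 48 h and 0 to 708 in the difference. In uninfected cells the slide as a block gave 4 and lmscFit 1164, and the other alternatives 0.

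Of 35 list shifts, 0 passed with an estimated correlation, which found 0 of 20 simulated shifts in genes drawn independently. Whether the preset correlation holds for genes that vary together was not tested. Counts of shifts under the other alternatives lay between 30 and 38. The same counts did not mean the same shifts. With median centring 38 were called, and 27 of the 35 were among them, while 4 of the 35 were lost and 4 changed test direction. The NRF2 difference lay between -0.49 and 0.056 and CDH1 at 24 h between -0.046 and 0.75 when 1 replicate was left out. The correlation of responses was 0.559 for 24 h replicate 2 with 48 h replicate 1. Of 622 values of 39 named genes at 24 h, 445 kept their direction and side of the threshold, and of 1520 values of 95 genes at 48 h, 1313. Between 78.9% and 87.7% of spots were well above background in Cy3, which limits values for the rest.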

Other observations

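All tests in this part were chosen after the result was seen: genes were grouped by the stem of their symbol into 220 families of at least 10 members and tested with camera, adjusted over families.

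Genes of intraflagellar transport, which carries cargo along the primary cilium, lay below 0 at 48 h in all 18 members of the IFT family, with a median of -0.50 (-0.53 and -0.43 in the replicates; adjusted p = 1.65e-05, and adjusted p = 0.924 with an estimated correlation). Of these, 8 fell, among them IFT70A at -0.99 ± 0.21, IFT70B at -0.90 ± 0.07, IFT74 at -0.75 ± 0.06 and IFT80 at -0.69 ± 0.03 (SD, n = 2). COMMD genes, whose products act in endosomal sorting, had a median of -0.62 (0.00646, and adjusted p = 0.924 with an estimated correlation), with COMMD8 at -0.96 ± 0.06, COMMD9 at -0.75 ± 0.12 and COMMD3 at -0.68 ± 0.17. Symbols of the large ribosomal subunit (RPL, median -0.21 over 59 with pseudogenes) and its mitochondrial counterpart (MRPL, -0.23 over 51 with a pseudogene and an antisense RNA) were both shifted down (adjusted p = 2.76e-05 for each, and adjusted p = 0.924 with an estimated correlation). Past the test over all genes, 5 RPL symbols fell and 2 rose, near the share of all genes that fell, and 8 MRPL symbols fell and 0 rose.

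TNF receptor genes (TNFRSF, 20 members) had a median of 0.34 at 48 h (adjusted p = 0.00390, and adjusted p = 0.924 with an estimated correlation), and 7 rose and 1 fell. TNFRSF6B, a decoy receptor, rose by 2.70 ± 0.67, TNFRSF11B, osteoprotegerin, by 1.96 ± 0.08, and the death receptors TNFRSF10A and TNFRSF10B by 1.50 ± 0.06 and 1.37 ± 0.16. Fucosyltransferase genes (FUT, 10 members with an antisense RNA) had a median of 0.67 (0.00582, and adjusted p = 0.924 with an estimated correlation), and FUT3, which makes Lewis antigens, rose by 0.90 ± 0.01 and FUT4 by 0.78 ± 0.15. KLF transcription factors, 16 symbols with the antisense RNA KLF3-AS1, had a median of 0.40 (0.00706, and adjusted p = 0.924 with an estimated correlation). The antisense RNA, at -1.07 ± 0.19, was the only 1 to fall. KLF6, KLF4 and KLF2 rose by 1.62 ± 0.35, 1.51 ± 0.16 and 1.35 ± 0.00.

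CEACAM adhesion genes (median 0.34, adjusted p = 0.0288) and keratins (KRT, 48 symbols with 5 pseudogenes and 1 antisense RNA, median 0.27, 0.0297) lost their shift with the slide as a block (0.0521 for both), and had an adjusted p = 0.924 with an estimated correlation. CEACAM1 rose by 1.89 ± 0.06 and CEACAM6 by 1.40 ± 0.04. Of the KRT symbols that rose 11 were keratin genes and 4 pseudogenes, and 3 keratins fell. KRT6B, of activated epithelium, rose by 2.54 ± 0.08, KRT6A by 1.11 ± 0.03 and KRT23 by 2.73 ± 0.97, while KRT4, of stratified mucosa, was at -1.14 ± 0.09, KRT15 at -0.84 ± 0.30 and KRT13 at -0.64 ± 0.12. The medians of these 9 families at 48 h kept their sign under each scaling tried, but not their size. With median centring, which moved the median of all genes to -0.13, RPL lay at -0.91, MRPL at -0.66 and FUT at 0.36, and with the scanner's processed signals TNFRSF lay at 0.68. At 48 h 8 families were shifted up and 18 down, and those not given above were mostly down, such as RPS, MRPS, COX, NDUFA, NDUFB, COQ and PEX. No family passed with an estimated correlation (lowest adjusted p = 0.924 at 48 h).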
